A study of Cereibacter sphaeroides with 5 samples.

How the data were processed

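Total RNA was measured on 5 one-colour Affymetrix arrays of a custom design for Rhodobacter sphaeroides, a purple photosynthetic bacterium. Per the labels, 2 arrays held the wild-type strain 2.4.1 (A1 and B2) and 3 held CT01 (A2, B1 and C1), a strain with an omega cassette for spectinomycin and streptomycin resistance inserted in RSP4157. Per the labels, both strains grew in the dark under 3% O2, with 96% N2 and 1% CO2 stated for every culture except CT01 C1. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

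The deposited values are linear probe set intensities, 1 per probe set and array. The algorithm that summarised the probes is not given in the sources used here. The deposited intensities carry 1 scaling per array, because the mean after leaving out the lowest and highest 2% of probe sets was 1000.2 on each array. Detection calls were not used here. The experiment files deposited for each array were read for the chip lot, the fluidics station and the order of scans, and gave no measurement. Per the file headers, the 5 arrays shared 1 lot and 1 day. Station 1 ran wild type A1, CT01 A2 and CT01 C1, and station 2 ran wild type B2 and CT01 B1, so each station held both strains.

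The table held 5355 probe sets, identified by number. The platform annotation ties 542 of them to 1 gene symbol each, 0 to several, and 4813 to none. A second entry for a threonine synthesis gene, with 3 probe sets and a sequence of its own, was treated as a control and left out, which left 5352 probe sets tested, 539 of them with a symbol, for 497 distinct symbols. Other control probe sets among the unnamed ones could not be told from genes. A RefSeq gene table of assembly ASM332471v1 held 492 of the 497 symbols and was used only for names, gene length, replicon and neighbourhood. No probe set is tied to RSP4157 or to the next genes RSP4158 and RSP4159, so the insertion itself was not checked on these arrays.

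The comparison was CT01 minus wild type. Array medians on the log2 scale differed by up to 0.16. This was above the tolerance of 0.1 set before the data were examined, so by that rule the arrays were quantile normalized, and log2(signal + 16) was analysed. The added 16 understates fold changes of dim probe sets. limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) tested each probe set, with Benjamini-Hochberg adjustment over all 5352 and a threshold of 0.05. No dim probe sets were removed. The number of arrays limits the precision. The median standard error was 0.18 on the log2 scale, 0.10 in the brightest 25% of probe sets and 0.28 in the dimmest 25%. The same steps were tested on simulated data for CT01 against wild type, with 5352 probe sets of which 200 were changed. They recovered 74% of the 2-fold changes, 98.1% of those above the median signal, and 99% of the 4-fold changes, with 11 false calls among 184. The simulated noise was normal, independent between probe sets, without a station effect, and took its spread from the same fit. These rates may thus be better than those on the real arrays. Plots were drawn with matplotlib 3.10.9.

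The rule for named genes, set before the data were examined, took RSP4157 to RSP4159, the 15 largest rises and 15 largest falls among probe sets past the threshold whose strains did not overlap, and up to 4 members with the smallest p of each gene list described. Of 20 gene lists set before the data were examined, 15 had at least 3 measured members. The lists were matched by symbol alone, because the tables used here pair probe sets with neither products nor these locus tags. Several probe sets of a gene were each counted. Lists, and replicons with at least 3 named probe sets, were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists or replicons. Calls were also repeated with an estimated correlation, and with limma's fry, in its directional form (whether members move on balance one way) and its mixed form (whether they change in either direction), neither of which compares a list with other genes. Counts per list are given over all probe sets and adjusted over the list alone.

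Alternatives set before the data were examined were the deposited scale, scaling to a common median, offsets of 1 and 64, removal of the dimmest 25% of probe sets, eBayes without a trend, robust eBayes, blocks by the letter or digit of the sample name or by fluidics station, only probe sets with 1 symbol, leaving out each array in turn, and random lists matched on signal. Taking 1 value per gene in the list tests was added after seeing the data. Whether called probe sets stand next to each other, or in runs with gaps of at most 8 numbers, was tested with 10000 random draws, also after seeing the data. Runs with gaps of at most 6 numbers were listed without a test. Among named probe sets on the chromosomes, consecutive numbers mostly followed the genome. This was not checked on the plasmids or inside the runs of falls, whose probe sets mostly have no symbol. Of 412 pairs of named probe sets next in number on chromosome 1, 89.8% lay within 50000 bp of each other in RefSeq, against 4.02% after shuffling, and on chromosome 2 it was 75% of 32 pairs, against 19.0% after shuffling.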

Results

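Transcript levels were compared between the CT01 insertion strain and the wild type 2.4.1 of R. sphaeroides, both grown in the dark at 3% O2, with 3 CT01 arrays and 2 wild-type arrays. The question, from the title of the series, is how the strains differ at low oxygen. Median signals were 538 and 479 in wild type A1 and B2, and 532, 504 and 518 in CT01 A2, B1 and C1. Signals ran from 0.2 to 52302, and the log2 values of any pair of arrays correlated at 0.96 to 0.981 across probe sets. The gene that carries the insertion has no named probe set, so its own level is not reported here.

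Few probe sets differed, and the median fall was larger than the median rise. In CT01 41 probe sets were lower and 32 were higher, of 5352 tested. The median fall was -2.15 on the log2 scale and the median rise 0.61. Of the falls, 34 reached 2-fold and 22 reached 4-fold, whereas 8 rises reached 2-fold and 0 reached 4-fold. The count of 4-fold rises depends on the offset, with 4 at offset 1 (against 23 falls) and 0 at offset 64 (against 19 falls), and it was 1 without wild type A1, wild type B2 or CT01 B1. Without wild type A1 or B2 the median fall of the fewer calls was -3.60 and -4.01 and the median rise 0.93 and 1.77. The strains did not overlap in any of the 73, a separation that 27.1% of all probe sets showed and that chance gives 20% of the time. At an unadjusted p under 0.05 there were 543 probe sets, against 267.6 by chance. In a model of strain and fluidics station together 640 were under 0.05 between strains. In that model, however, 589 were also under 0.05 between the stations, where 0 passed the adjusted threshold. With the fluidics station as a block 38 were lower and 22 higher, of which 37 and 18 were among the 73. At stations 1 and 2 the medians of the falls were -2.09 and -2.23 and those of the rises 0.55 and 0.67. The higher share was 43.8%, but 23.5% when arrays were scaled to a common median, with 12 higher and 39 lower. Without wild type A1, wild type B2, CT01 A2, CT01 B1 or CT01 C1 the higher calls numbered 5, 3, 5, 10 and 9, and the lower calls numbered 19 without wild type A1 and 14 without wild type B2.

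Among the genes with a symbol, repC fell and rpmH, trxA and tatA rose. repC encodes a replication initiator of plasmids, and its signal was 504.9 ± 2.69 (SD, n = 2) in wild type and 24.4 ± 5.78 (SD, n = 3) in CT01, a change of -3.75 ± 0.23 (SE) on the log2 scale (adjusted p = 0.00028). The size depends on the offset because the CT01 signal is dim, with -4.41 at offset 1 and -2.72 at offset 64. rpmH, which encodes a protein of the large ribosomal subunit, rose 1.78-fold (log2 change 0.83 ± 0.08, SE, adjusted p = 0.00218). trxA, which encodes thioredoxin, rose by 0.56 ± 0.09 (SE) on the log2 scale (adjusted p = 0.0258), and tatA, of the twin-arginine protein export system, by 0.35 ± 0.06 (SE, adjusted p = 0.028). repC held under all 15 alternatives, rpmH under 15 of 16, the exception being eBayes without a trend (adjusted p = 0.0747), trxA under 9 of 16 (0.00513 to 0.26) and tatA under 5 of 16 (0.00835 to 0.476). trxA was lost without wild type A1 (0.139), wild type B2 (0.191), CT01 A2 (0.0587) or CT01 B1 (0.0904), and tatA without any of the 5 arrays in turn (0.124, 0.186, 0.0913, 0.0776 and 0.0998 in the order wild type A1, wild type B2, CT01 A2, CT01 B1, CT01 C1). With the station as a block the adjusted p was 0.0585 for trxA and 0.0607 for tatA, with changes of 0.56 and 0.54 (trxA) and 0.33 and 0.37 (tatA) at the 2 stations.

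**Figure D1:**
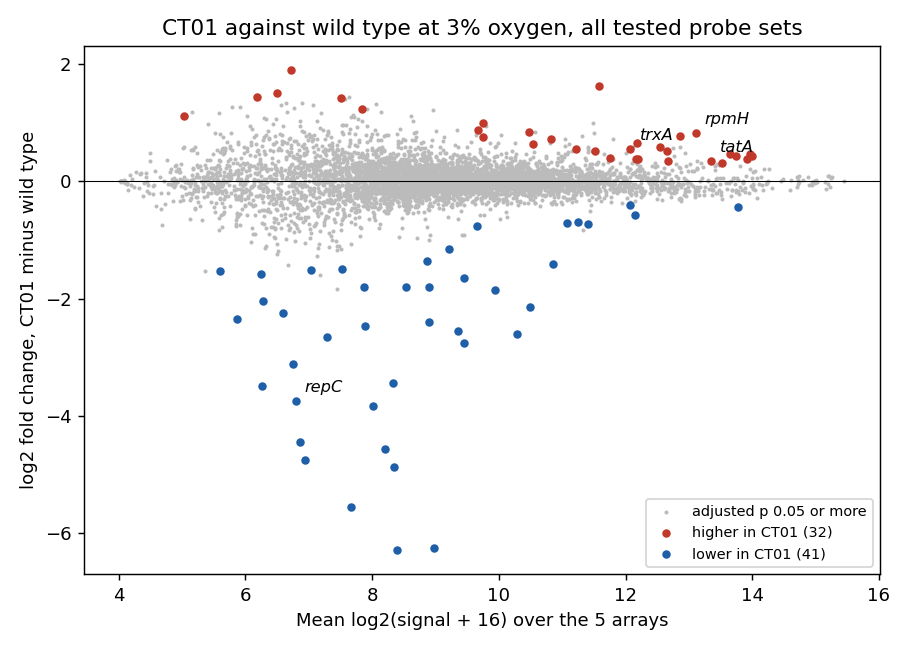
Log2 fold change of CT01 minus wild type (vertical axis) against the mean log2(signal + 16) over the 5 arrays (horizontal axis) for 5352 probe sets, with 32 higher in CT01 in red and 41 lower in blue. The falls reach -6.29 and the rises 1.90, and the 4 called genes with a symbol are written in.

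The strongest changes lay in probe sets that the annotation leaves without a gene. Probe set 4886 fell by 6.29 ± 0.21 (SE) on the log2 scale, from a mean signal of 4689 to 43.9 (adjusted p = 2.54e-05). Probe set 819 fell by 6.25 ± 0.27 (SE) on the log2 scale (adjusted p = 5.48e-05). With offset 64 these values were -5.44 and -5.63, and with offset 1 -6.70 and -6.52. Among the rises, probe set 2004 went up 3.10-fold from a mean signal of 1562 to 4797 (log2 change 1.63 ± 0.13, SE, adjusted p = 0.00121). Probe set 1003 rose by 1.90 ± 0.28 (SE) on the log2 scale from a dim signal of 30.7 (adjusted p = 0.0222). Which rise is largest depends on the offset, since probe set 1003 was at 1.25 and probe set 2004 at 1.60 with offset 64, and probe set 1003 was at 2.31 and the dim probe set 117 at 2.41 with offset 1. The call of probe set 1003 was lost without wild type A1 (0.106), wild type B2 (0.186), CT01 A2 (0.0685) or CT01 C1 (0.0997), over a range of 0.0187 to 0.186 across its alternatives, while probe sets 4886, 819 and 2004 kept theirs under all 15. Of the 73 called probe sets, 3 rises and 1 fall carry a symbol.

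Many falls were neighbours by probe set number, a feature looked for after the values were seen. A stretch from the repC probe set, number 4865, to number 4887 held 9 of the 41 falls, and all 23 of its members had negative values (median -0.97). It is 1 run with gaps of at most 8 numbers. With gaps of at most 6 it splits into 4865 to 4870 (4 called) and 4877 to 4887 (5 called). Between these, 4871 to 4874 had values of -0.24 to -0.14, and 4875 and 4876 had -0.83 and -0.92, none of them called. The 46 probe sets on both sides of the stretch had a median of -0.01, and 0 of them were called. At stations 1 and 2 the median of the stretch was -0.77 and -1.34. In wild type 8 members were above the median of all probe sets, and 0 in CT01. The 9 called members had mean CT01 signals of at most 117.4, whereas 7 of the 14 others had CT01 signals above 200, the highest 364. Other runs are given here with gaps of at most 6 numbers. Numbers 1916 to 1919 were all called (median -2.57), as were 4 of the 6 from 5133 to 5138 (median -1.21) and 3 of the 4 from 422 to 425 (median -2.02). With gaps of at most 8 this last run reaches 433, since 432 and 433 were also called (-1.53 and -4.44).

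**Figure D2:**
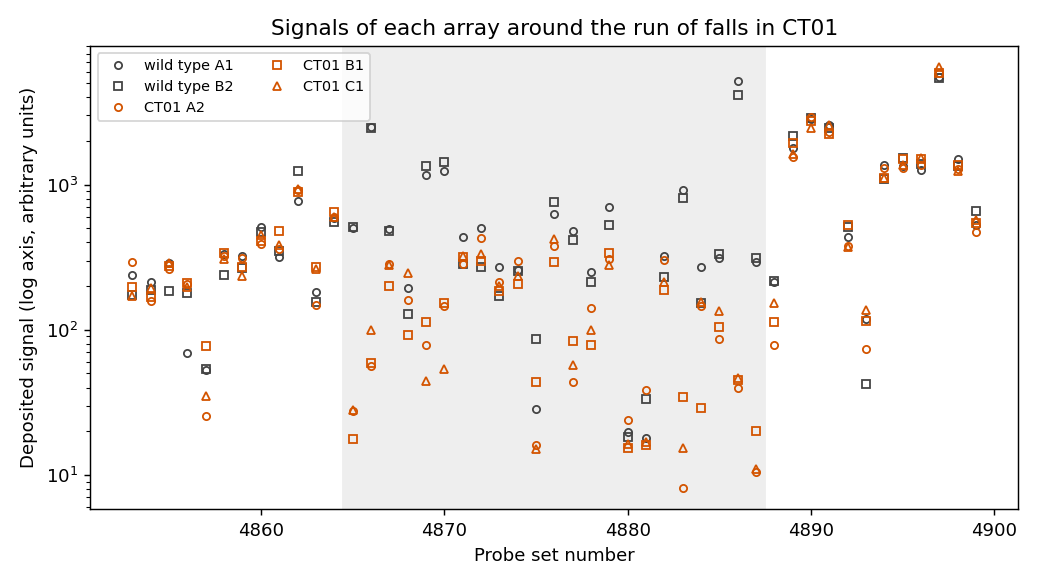
Deposited signal (log axis, arbitrary units) of each array for the probe sets around the longest run of falls with gaps of at most 8 numbers, by probe set number. The wild type is in grey and CT01 in orange, and the marker gives the array. The shaded part runs from 4865 to 4887, where 8 members are above the median of all probe sets in wild type and 0 in CT01.

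Genes of the photosynthetic apparatus lay slightly lower in CT01 as groups, with 0 single members past the threshold over all probe sets, although pufM passed under 3 of 16 alternatives (lowest adjusted p = 0.0183) and bchL under 1 (0.0478). The list of light-harvesting and reaction centre genes (11 probe sets of 7 genes) had a median of -0.15, with 7 values negative (camera adjusted p = 0.018). The call was lost, with adjusted p = 0.353 with an estimated correlation. Adjusted over the list alone, 4 fell and 0 rose, namely pufM (-0.29 ± 0.06, SE), which encodes a reaction centre subunit, puhA (-0.24 ± 0.08), which encodes another, pufX (-0.20 ± 0.06) and pufQ (-0.20 ± 0.06). The annotation ties 5 probe sets to pufA, and these had values from -0.10 to 0.09. Mixed fry passed for this list (adjusted p = 0.00162) and directional fry did not (0.209). The bacteriochlorophyll and haem list (23 probe sets of 19 genes, 5 of them tied to bchF) had a median of -0.13 with 21 values negative (camera adjusted p = 0.00064, and adjusted p = 0.353 with an estimated correlation). Over all probe sets 0 of its members fell, and adjusted over the list alone 1 did, bchL (-0.35 ± 0.07, SE), of the light-independent protochlorophyllide reductase. Fry passed in neither form for this list (0.216 directional, 0.352 mixed). hemN had a value of -0.28, bchE -0.17 and bchJ -0.33. The station medians were -0.18 and -0.13 for the first list and -0.12 and -0.11 for the second. The first call was also lost on the deposited scale (0.0504), after scaling to a common median (0.0998), with only probe sets that have a symbol (0.102), against random lists (0.078) and without wild type A1 (0.323), within a range of 0.000572 to 0.353 over its alternatives.

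Regulators of photosynthesis genes lay slightly higher (20 probe sets of 8 genes, median 0.12, 18 positive, camera adjusted p = 0.0154, and adjusted p = 0.437 with an estimated correlation). Adjusted over the list alone 0 members changed, and 0 did over all probe sets. The oxygen regulator gene fnrL, the gene of the redox and light sensor AppA and the gene of the repressor PpsR have 5 probe sets each. The probe sets with the smallest p had values of 0.21 and 0.17 for fnrL, 0.17 for appA and 0.15 for ihfA. With 1 value per gene the call was lost (0.176), and so it was on the deposited scale (0.0504), with a common median (0.242), without wild type A1 (0.472) and without CT01 B1 (0.119), within a range of 0.000206 to 0.472. Fry passed in neither form (0.544 directional, 0.586 mixed), and the station medians were 0.16 and 0.11. The 7 probe sets for carotenoid synthesis had a median of -0.07 and no call (camera adjusted p = 0.352), a median that turned to 0.01 without CT01 C1.

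In central carbon metabolism and respiration the values were small and mostly negative. The list for the TCA cycle and related carbon steps (8 probe sets of 8 genes, the symbols sdhA and fumC each covering 2 of them) had a median of -0.14 with 6 values negative (camera adjusted p = 0.049, and adjusted p = 0.437 with an estimated correlation). Of its members 0 fell over all probe sets and 1 fell adjusted over the list alone, sucC (-0.27 ± 0.06, SE), which encodes a subunit of succinyl-CoA synthetase. Values of gltA, mdh and 1 of the sdhA probe sets were -0.13, -0.19 and 0.40. This call was lost under 12 of 19 alternatives (0.0168 to 0.442), including without wild type A1 (0.442), CT01 B1 (0.151) or CT01 C1 (0.0514), and fry passed in neither form (0.589 directional, 0.675 mixed). The TCA call was also lost on the deposited scale (camera adjusted p = 0.0504), with a common median (0.0998) and with only probe sets that have a symbol (0.238). The station medians were -0.13 and -0.20. Terminal oxidases and cytochromes (7 probe sets, median -0.08) did not pass (camera adjusted p = 0.0538), but did under 5 of 19 alternatives, namely offset 1 (0.0477), the dimmest 25% left out (0.0399), the block by letter (0.0365) or digit (0.0483) and without CT01 C1 (0.021), within a range of 0.021 to 0.572. The block by letter and the setting without CT01 C1 compare the strains on the same arrays (medians -0.177 and -0.176), so they are not separate. Adjusted over the list alone 1 of the 7 probe sets fell, ccoN (-0.30 ± 0.06, SE), which encodes the catalytic subunit of the high-affinity cytochrome oxidase, against 0 over all probe sets, although ccoN passed there under 3 of 16 alternatives (lowest 0.0231), and ccoP, ccoO and ccmB had values of -0.24, -0.18 and 0.13. NADH dehydrogenase (9 probe sets, median -0.01) and ATP synthase (4 probe sets, median -0.12, the symbols atpA and atpD each covering 2 genes) did not pass (camera adjusted p = 0.765 and 0.291), and the median of the former was 0.02 without wild type B2.

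Ribosomal protein genes had mostly slightly negative values, while rpmH rose. Of 45 probe sets, 1 for each gene, 31 had negative values (median -0.09, camera adjusted p = 0.0206, and adjusted p = 0.353 with an estimated correlation). Over all probe sets 1 rose, rpmH, and 0 fell, and adjusted over the list alone 3 rose (rpmH, rpsO at 0.21 and rpmB at 0.30) and 2 fell (rpsJ at -0.22 and rpmA at -0.23). The call was lost without wild type B2 (0.219) and under 7 of 19 alternatives (0.0172 to 0.353), and the station medians were -0.06 and -0.07. Those 7 included the deposited scale (camera adjusted p = 0.0504), a common median (0.0724) and only probe sets that have a symbol (0.24). Named probe sets as a whole lay slightly lower, with a median of -0.034 over 539, against 0.002 over all 5352. Camera calls of lower lists against all probe sets can therefore take in part of that shift. Translation factors and RNA polymerase (12 probe sets, 2 of them for rpoB, median -0.10, camera adjusted p = 0.0777) had 0 changes over all probe sets. Adjusted over the list alone 2 rose (rpoZ at 0.20 and infA at 0.22) and 3 fell (rpoC at -0.35, infC at -0.34 and tsf at -0.21). In heat shock proteins (10 probe sets, the symbol groEL covering 2 genes, median -0.05, camera adjusted p = 0.0653) 0 changed over all probe sets, and adjusted over the list alone 1 fell, dnaK (-0.36 ± 0.07, SE), a chaperone gene that also passed among only the probe sets with a symbol (0.0476), beside clpA at -0.60, groEL at -0.14 and lon at -0.16. Mixed fry passed for ribosomal proteins, translation factors and RNA polymerase, and terminal oxidases (adjusted p = 0.00162, 0.0083 and 0.0205), and directional fry for none of them (0.277, 0.209 and 0.244).

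Other groups did not pass. In the oxidative and singlet oxygen stress list (7 probe sets, median 0.08, camera adjusted p = 0.371) trxA was the 1 member that rose, over all probe sets and adjusted over the list alone, with grxC at 0.24, chrR at -0.78 and gor at -0.10. Mixed fry passed for this list (adjusted p = 0.0205) and directional fry did not (0.544). Of the 15 lists, none passed directional fry, with adjusted p from 0.209 to 0.963, and the lists whose mixed value is not given here lay above the threshold, the lowest being heat shock proteins (0.0534). The medians were -0.03 for nitrogen fixation and hydrogenase (21 probe sets, adjusted p = 0.502), 0.02 for flagellum and chemotaxis (23 probe sets, 2 each for fliM, flgL and flhB, adjusted p = 0.765) and 0.02 for iron uptake and iron-sulfur assembly (8 probe sets, the symbol bfr covering 2 genes, adjusted p = 0.765), each from camera, with 0 members changed over all probe sets and 0 adjusted over the list alone. The nitrogen fixation median was 0.00 on the deposited scale and the iron median -0.03 after scaling to a common median. Without CT01 C1 the flagellum and iron medians were -0.19 and -0.01, and the oxidative stress median was -0.05 without CT01 A2. At the 2 stations the medians had opposite signs for flagellum (0.23 and -0.26), iron (0.07 and -0.07), oxidative stress (0.05 and -0.07) and NADH dehydrogenase (0.015 and -0.029). Lists with fewer than 3 measured members were not tested. Their members had values of -0.16 (cbbX) and 0.29 (cbbR) in the Calvin cycle, 0.02 (gloB) and -0.01 (gph) in glycolate metabolism, -0.38 (phaC) in polyhydroxybutyrate synthesis, and -0.25 (dorS) and -0.06 (dorR) in anaerobic respiration. None of 4 replicons shifted by camera over its named probe sets, with medians of -0.03 (chromosome 1, 472 probe sets), -0.05 (chromosome 2, 34), -0.20 (pA, 5) and -0.25 (pDE, 4), adjusted p = 0.284 to 0.314, and 0 had an unadjusted p under 0.05. These sets held 0 of the probe sets called lower, so repC and the unnamed falls were not covered. Fry, which does not compare a replicon with the others, passed for pDE in its directional form (adjusted p = 0.017, mixed 0.467) and for chromosome 1 in its mixed form (0.00146, directional 0.21), and in neither form for chromosome 2 (0.338 and 0.661) or pA (0.218 and 0.447).

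**Figure D3:**
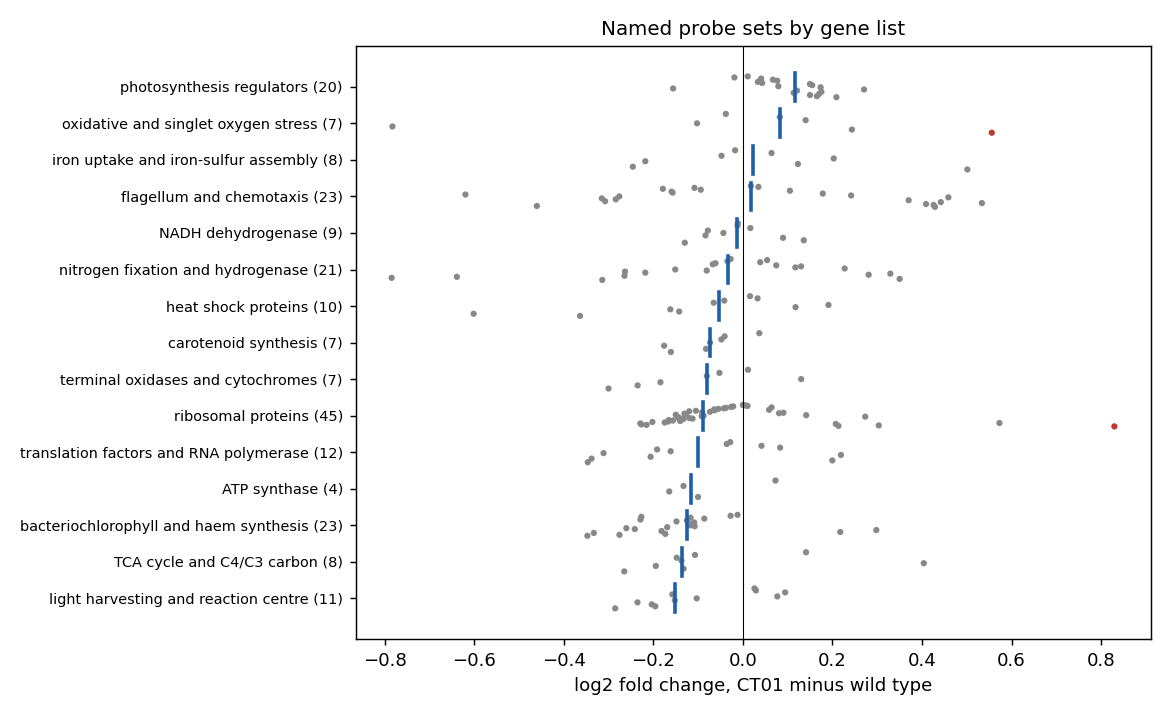
Log2 fold change of CT01 minus wild type (horizontal axis) for each named probe set in the 15 tested gene lists, with the number of probe sets in brackets and the median of each list as a blue bar. Red points are the members past the threshold over all probe sets, trxA and rpmH, and list medians lie between -0.15 and 0.12.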

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

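The alternatives were set before the data were examined, except 1 value per gene, chosen after seeing the data. Of the 41 falls 36 were called again on the deposited scale and 38 with a common median, and of the 32 rises 20 and 12. The number of lower calls stayed within 1.5 times of 41 except with only the named probe sets (5, of 539 tested), without wild type A1 (19) and without wild type B2 (14), and without 1 array it ran from 14 to 32. The 32 higher calls became 12 with a common median, 10 without a trend in eBayes, 3 with only the named probe sets, and 3 to 10 without 1 array (5, 3, 5, 10 and 9 without wild type A1, wild type B2, CT01 A2, CT01 B1 and CT01 C1). Where 1 wild-type array was left, it was assumed to vary like CT01. The labels do not say that the letters or digits in the sample names pair samples. With the replicate block by letter 10 were higher and 32 lower, and by digit 18 and 35. Deviations from the strain means correlated at 0.14 for A1 with A2 and 0.29 for B2 with B1, but also at 0.16 for A1 with C1, and these 3 pairs each share a fluidics station. Since the wild type has only A1 and B2, their deviations are equal with opposite signs, and those of the CT01 arrays cancel out. The 3 values are therefore not independent, and no conclusion on pairing or station is drawn from them.

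The number of lists past the threshold, 5, became 1 on the deposited scale, 1 with a common median, 2 with only the named probe sets, 0 with an estimated correlation, 2 against random lists, 3 with 1 value per gene, and 2 to 5 without 1 array (2 without wild type A1, 3 without CT01 B1). List medians without a call changed sign as follows: nitrogen fixation to 0.001 on the deposited scale, iron to -0.025 with a common median, flagellum to -0.004 with offset 64, and, with the block by letter, carotenoid to 0.007, flagellum to -0.182 and iron to -0.008. Without 1 array the medians ranged from -0.049 to 0.023 (NADH dehydrogenase), -0.048 to 0.177 (oxidative stress), -0.127 to 0.006 (carotenoid), -0.187 to 0.175 (flagellum) and -0.008 to 0.051 (iron), and gor from -0.222 to 0.015. Leaving out arrays or probe sets leaves fewer values by construction. So does the block by letter, since CT01 C1 is the only array with its letter and adds nothing to the strain difference there. Changes of sign with that block thus repeat those without CT01 C1 and are not separate. For the other settings the cause was not tested. Dim probe sets limit what can be called, with a median standard error of 0.28 in the dimmest 25%.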

Other observations

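The tests on neighbouring numbers and on the run of falls were chosen after the result was seen, as were the leaving out of arrays from the length trend, the final form of the length correction and the bound for the random lists, a comparison that was itself planned.

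Some called probe sets stood side by side, more pairs of falls than of rises. Probe sets 1482, 1483 and 1484, all bright, rose by 0.38, 0.43 and 0.46 on the log2 scale, and 2004 and 2005 by 1.63 and 0.72. Among the 32 rises 3 pairs had consecutive numbers, against a mean of 0.182 in 10000 random draws (permutation p = 7e-04), and among the 41 falls 14 pairs had, against a mean of 0.298 (permutation p = 1e-04, the smallest possible). These draws, and those for the run below, treat each probe set as separate, whereas several probe sets of 1 gene can have consecutive numbers, such as pufA (1126 to 1130). The p-values thus do not tell repeated measures of 1 gene, or neighbouring genes that change together, from separate changes. The 5 rises named have no symbol here. Among the 539 named probe sets, 68 had an unadjusted p under 0.05, and 3 rises and 1 fall passed the adjusted threshold.

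The run of falls from the repC probe set to number 4887 was weighed against technical explanations. With gaps of at most 8 numbers it held 9 of the 41 falls, against at most 5 in the longest run of each of 10000 random draws (permutation p = 1e-04, the smallest these draws can give). This argues against chance placement at that gap only, which was chosen after the falls were seen. With gaps of at most 6 the run splits into 4865 to 4870 (4 called) and 4877 to 4887 (5 called), for which no draws were made. The 14 side-by-side pairs of falls, against at most 4 in the draws, need no gap setting. Each station held both strains, so a station difference alone could not give falls within a station. The weaker of the station medians was -0.77, which argues against the station as the only source. The run was, however, chosen by its falls in these same arrays. CT01 may have lost a piece of DNA that starts near repC, as a hypothesis, but the 0 members above the median in CT01 do not count for it, since the run was chosen by its falls. Whether numbers 4865 to 4887 lie side by side in the genome was not checked either. The order of the members by signal was lost in CT01 (Spearman rho 0.137 across probe sets, which are not independent replicates, 95% bootstrap interval -0.297 to 0.554), but all 9 called members lay in the dimmest 25% there, where any deep fall would scramble the order. The signals themselves did not fall by 1 common fold. Number 4872 went from a mean of 387 in wild type to 353 in CT01 (log2 change -0.14), while repC went from 505 to 24 (-3.75). Loss, 1 common fold of the transcripts and separate lower transcription cannot be told apart, since the background of each probe set is not known.

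Among named genes a weak trend with gene length was larger against 1 wild-type array than against the other (Spearman rho of log2 change and length -0.102 across 491 probe sets, 95% bootstrap interval -0.188 to -0.016, permutation p = 0.025). The intervals and this p treat probe sets as independent and do not measure the spread between arrays. Genes of up to 741 bp and genes from 1221 bp had similar median changes, -0.027 and -0.043. A difference between arrays that depends on length may thus be present. The trend was -0.134 at station 1 and -0.045 at station 2 (interval -0.13 to 0.04), too wide to settle a part of the station. The trend followed wild type A1 more than the station, with -0.091, -0.125 and -0.13 for CT01 A2, B1 and C1 minus A1 and -0.032, -0.045 and -0.027 for the same arrays minus B2. Without A1 it was -0.044 (interval -0.135 to 0.04) and without B2 -0.151 (interval -0.235 to -0.064), and these intervals overlap. Between arrays of 1 strain the largest size was 0.043, for the wild-type pair, too close to the value between strains for its spread to decide. A linear length correction among the 491 changed some list calls. Ribosomal proteins went from camera adjusted p = 0.237 to 0.00459 and light harvesting from 0.0982 to 0.00223, while the TCA list passed neither before nor after (0.237 and 0.336). Ribosomal proteins and light harvesting hold mainly short genes (median lengths 375 and 234 bp). A correction with a negative slope lowers short genes by construction, so no conclusion is drawn from these passes.

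The lower values of the bacteriochlorophyll and haem list remained after a length correction, but this correction could move them only slightly. The fitted slope was -0.028 on the log2 scale per doubling of length. The median length of the list, 963 bp, was neither short (up to 741 bp) nor long (from 1221 bp) among the named genes. The correction therefore cannot decide whether length is a source, and no conclusion is drawn from it. The median log2 change of the list was -0.12 before and -0.15 after the correction (22 of 23 probe sets with a length, limma's camera adjusted p = 0.0133 among the 491). It lay at percentile 0.21 of 10000 random lists matched on signal, which argues against the signal level. Since camera with an estimated correlation gave adjusted p = 0.353 for this list, genes that vary together between arrays remain open as a source, and a lower expression in CT01 is a hypothesis only.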
